A study of Mus musculus with 8 samples.

How the data were processed

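The series holds single-cell RNA libraries from lung adenocarcinomas of KPC mice. CRISPR activation was aimed at tumour cells from the start of tumour formation, with dead guide RNAs against Malat1 (labelled mA1) or against Tomato (labelled Con), and the largest tumours were taken 16 weeks later. Per the labels, 4 tumours of each group were dissociated with collagenase IV and DNase, dead cells were removed, and cells were tagged with 1 of 2 hashtag antibodies against CD45 and MHC class I before 10x 3' version 3 libraries were made. Each group has 2 libraries, so a tumour was taken to be the cells of 1 library that carry 1 hashtag. The labels do not say whether the 2 hashtags of a library are separate animals, so p-values may measure only the spread between these samples. The tumours were chosen as the largest, and the submitters' criteria beyond size are not given in the sources used here.

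The deposited matrices hold UMI counts, 1 matrix per library, made with Cell Ranger 6.0.1 per the file headers and the submitters' processing notes, which also name the mm10 genome build. Whole-number values and library totals were checked on each file. Each matrix has 32286 gene features, among them an EGFP sequence whose source the labels do not name, and 19 antibody features. Of these only the 2 hashtags hold counts, apart from 3 counts of CD16 in mA1 library 1. Malat1 lies on chromosome 19 of GRCm38 (mm10), from 5795690 to 5802672, and is annotated as lncRNA. The files held 10168 and 4939 barcodes for the 2 mA1 libraries and 8842 and 7135 for the 2 Con libraries, with 73377111, 48319272, 74996867 and 54397659 UMIs.

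Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs, which left 7735, 3898, 7397 and 5808. The mitochondrial limit removed the most barcodes, with 23.3%, 19.7%, 15.4% and 17.7% above it. Hashtags were called by a Gaussian mixture of 2 components on the log10 counts of each library and hashtag, at a posterior of 0.5. The share of cells with exactly 1 hashtag was 84.4%, 78.9%, 84.1% and 87.1%, and cells with both hashtags (226, 87, 245 and 145) were left out as doublets. Scrublet (scanpy 1.11.5, expected rate 0.008 per 1000 cells) called 171, 31, 77 and 0 cells, part of them among those with both hashtags, and all were left out. In Con library 2 it marked 0% of the cells with both hashtags, against 30.1%, 19.5% and 13.5% in the other libraries, so it was taken not to have worked there. The both-hashtag cells imply about 261, 87, 329 and 183 doublets within tumours, so an alternative left out as many top-scoring cells. After this, 7406, 3797, 7108 and 5663 cells remained. Tumours held 1458 to 4272 cells and 14459792 to 37954201 UMIs.

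Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were taken within libraries, leaving out Malat1, EGFP, antibody features, mitochondrial and ribosomal protein genes. Xist was among the variable genes of the clustering of all cells, and the Y-linked genes and Xist were left out of the sub-clusterings. Clusters came from 30 principal components, 15 neighbours and the Leiden method at resolution 1, without integration (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, umap-learn 0.5.12, numpy 2.4.6, pandas 2.3.3, python 3.11.15). Clusters were named from fixed marker sets and the 10 genes leading each cluster by fold. Clusters 15, 17, 19, 26, 28, 29 and 31 fitted no marker set or held too few UMIs or cells and stayed unnamed. Macrophage cluster 6 kept its number, because its leading genes hold a dendritic cell marker (Ccl17) and no alveolar macrophage marker, although all 8 alveolar macrophage markers were detected in it. Names rebuilt this way may differ from the submitters' own. Tumour-like epithelial cells, and the monocyte and macrophage classes, were clustered again at resolution 0.5.

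UMIs were summed per tumour and class and tested with edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, robust quasi-likelihood, two-sided) for the 11 classes with at least 20 cells per tumour, or per library. Error terms of log2 fold changes are standard errors from that model. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The design fixed tumours as replicates for every class. Tumour-like epithelial cells carried 1 hashtag in only 18.6% of cells and could not be tested that way with the hashtag call fixed, because too few tumours held 20 of them, so the 2 libraries of each group were their replicates. The epithelial pseudobulks held 5854540 to 15599600 UMIs in 139 to 537 cells, those of alveolar macrophage-like cells 4596940 to 17419400 UMIs in 273 to 1116 cells, and those of NK-like cells 210616 to 1674660 UMIs in 72 to 531 cells. Shares of classes and states were compared by exact two-sided permutation of the 8 tumours (70 arrangements, smallest p 0.0286) or of the 4 libraries (smallest p 0.333). Groups of 4 tumours part without overlap in 2.86% of arrangements and groups of 2 libraries in 33.3%.

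Before the data were examined, 34 gene lists were fixed, covering chemokines, inflammatory cytokines, NF-kB response, interferon response, MHC class I, MHC class II, hypoxia and glycolysis, EMT and invasion, AT2 identity, tumour progression states, cell cycle, p53 targets, inflammatory, alternative and lipid-associated macrophage genes, monocyte recruitment receptors, immune checkpoints, T cell cytotoxicity, T cell exhaustion, naive T cell, regulatory T cell, neutrophil activation, matrix and fibroblast activation, endothelial activation, Malat1 neighbours, nuclear long RNAs, splicing factors, dissociation and immediate early genes, ribosomal proteins, mitochondrial genes, and free RNA of AT2, myeloid, blood and plasma cells. Lists with at least 5 measured members were tested with limma 3.58.1 (camera, correlation 0.01), again with an estimated correlation, and by fry, adjusted over lists within a class. The rule for named genes was fixed at the same time. In tumour-like epithelial and alveolar macrophage-like cells it takes 12 genes always (Malat1, Neat1, Ccl2, Ccl7, Cxcl1, Cxcl2, Il1b, Tnf, Spp1, Arg1, Cd274, Ccr2), the 8 largest rises and falls among called genes with an average log2 CPM of at least 5 and no overlap of groups, and up to 3 called members per list. Other classes take 5 and 5, and where fewer genes pass, the 5 with the smallest p are given as not passing. Called genes outside that rule were named after their values were seen.

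The alternatives were edgeR with RLE factors, DESeq2 1.42.0, no low-count filter, stricter cells (1000 UMIs, 10% mitochondrial), doublets kept, a hashtag call at 10 counts and 80% of counts, Leiden resolutions of 0.5 and 2, equal cell numbers, libraries as replicates, blocks by library number, and each tumour or library left out. Alternatives chosen after the data were seen were the top-scoring doublets left out, neighbouring clusters merged, the Xist-expressing Con library left out, a crossed block for neutrophils, tumours by the 80% rule for the Malat1 difference, cells with at least 10 hashtag counts, and epithelial states found without the called genes. Malat1 was also compared after each cell was thinned to 1000 UMIs. The test was checked on simulated data. Negative binomial counts were drawn from the mean levels, library sizes and dispersions of the real pseudobulks, without library or tumour structure. A changed level was given to 200 genes with a mean of at least 32 CPM, so recovery below that level was not checked. At a log2 change of 1 it recovered 72% in epithelial cells (libraries), 96% in alveolar macrophage-like and 90% in NK-like cells, and 12.8%, 7.11% and 5.00% of the calls were false. A raised list of 20 genes was called in each, and 0 of 20 other lists were. Simulated genes varied independently, so this cannot show how often lists of correlated genes are falsely called. Figures were drawn with matplotlib 3.10.9, and the permutation tests used scipy 1.17.1.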

Results

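Single-cell RNA libraries from 4 tumours with Malat1-directed guides (labelled mA1) and 4 with control guides (labelled Con) were compared for Malat1 itself, for the tumour cells, and for the immune cells around them. The largest class was alveolar macrophage-like with 5555 cells, followed by CD4 T-like (2897), B cell-like (2442), neutrophil-like (2144), NK-like (1850) and CD8 T-like (1694) cells. Tumour-like epithelial cells, led by Krt7, Krt8, Krt18 and Cldn4, numbered 996, with a median of 30474 UMIs per cell, the highest among the named classes. Both tumours of Con library 2 expressed Xist (1297 and 1294 CPM) with Y-linked genes near 0, whereas the other 6 tumours had Xist at or below 1.66 CPM and Ddx3y at 42.5 to 61.0 CPM.

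Malat1, the long noncoding RNA that the guides target, showed no rise that passed the test in the tumour-like epithelial cells of the mA1 libraries. It made up 4.07% and 2.64% of the UMIs of these cells in the Con libraries and 2.59% and 4.50% in the mA1 libraries (3.35 ± 1.01% against 3.54 ± 1.35%, mean ± SD, n = 2 libraries per group). The edgeR log2 fold change was 0.10 ± 0.36 (SE; adjusted p = 0.963), and each of the 2 groups held 1 high and 1 low library. With an error of this size and 2 libraries per group, the test cannot exclude a modest rise. With every cell thinned to 1000 UMIs, the mean was 38.6 Malat1 UMIs in Con and 40.9 in mA1 cells, a log2 ratio of 0.08, with 1 cell too shallow to enter. Epithelial cells with an EGFP UMI held more Malat1 than those without in each library, at 4.55% against 3.97%, 2.72% against 2.48%, 2.74% against 2.52% and 5.12% against 4.04%, and they were also deeper in each (for example, medians of 36354 and 23162 UMIs in Con library 1). Since no rise in Malat1 passed the test, mA1 below names the libraries that carry this label, and every direction given is that of mA1-labelled against Con-labelled samples. The sign turned without Con library 2 (log2 fold change -0.16) and without mA1 library 2 (-0.45), and with hashtags called at 80% of counts, which allows 3 tumours per group, the value was 0.41 (adjusted p = 0.857).

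No other class passed the test for Malat1 either. Its log2 fold change was 0.06 in alveolar macrophage-like cells (adjusted p = 0.925), 0.25 in macrophage cluster 6 (0.972), -0.01 in C1q macrophage-like (0.999), -0.09 in neutrophil-like (1.00), -0.01 in cDC2-like (0.999), 0.06 in B cell-like (0.906), -0.05 in NK-like (0.919), 0.05 in CD4 T-like (0.901), -0.01 in CD8 T-like (0.989) and -0.05 in gamma-delta T-like cells (0.985). Its level differed far more between classes than between groups, from 1.08% of UMIs in macrophage cluster 6 to 4.14% in NK-like cells of Con tumours, where mA1 tumours had 1.30% and 3.93%. The log2 level in epithelial cells relative to the mean of the 10 other classes was 0.60 in Con and 0.69 in mA1 libraries, a difference of 0.09 (exact two-sided permutation p = 1, n = 2, smallest possible 0.333). On tumours by the 80% rule, chosen after the data were seen, the difference was 0.28 (exact p = 0.3, n = 3) and positive against each of the 10 classes, with 0.29 against alveolar macrophage-like cells (exact p = 0.1, the smallest possible with 3 per group; adjusted p = 0.55). Neat1, the nuclear RNA encoded next to Malat1, had a log2 fold change of -0.12 ± 0.21 in epithelial cells (adjusted p = 0.919).

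**Figure D1:**
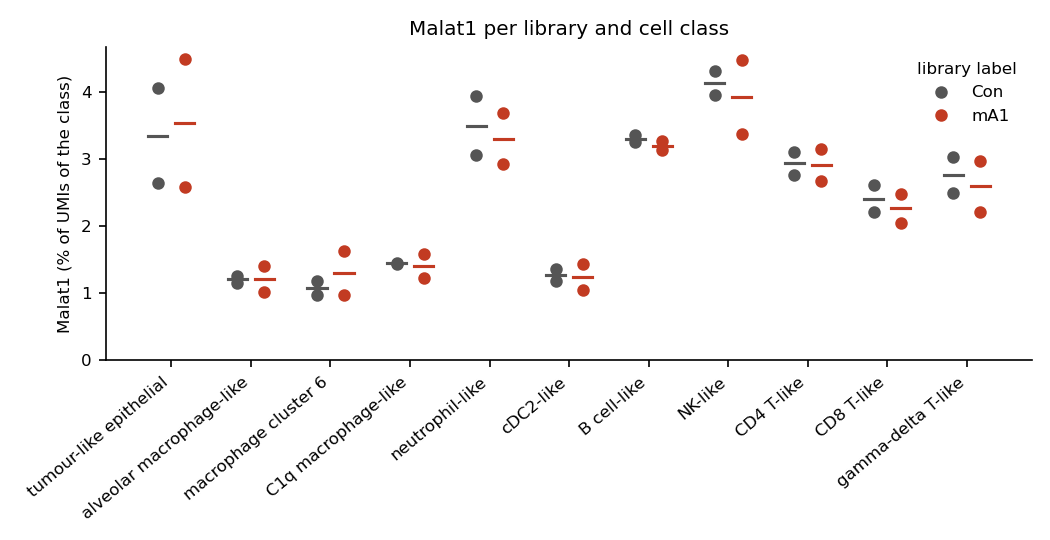
Malat1 as a percent of all UMIs of a class, per library and for each class tested. Each point is 1 library, bars mark group means, and the points of the Con and mA1 groups overlap in the tumour-like epithelial cells.

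The genes around Malat1 on chromosome 19 were tested as a list because activation at a promoter can act on its neighbours. Of 13 measured in epithelial cells, none passed the test, over all genes or over the list alone, and 12 had a positive log2 fold change (median 0.26). Cdc42ep2, which encodes an effector of Cdc42, was at 0.73 ± 0.23 (SE; adjusted p = 0.504), followed by Ehbp1l1 at 0.67 (0.553) and the kinase gene Map3k11 at 0.62 (0.553). As a set they were higher by camera (adjusted p = 0.00305), a call lost with an estimated correlation (adjusted p = 0.815 with an estimated correlation). The median was 0.07 without mA1 library 2 and 0.45 without Con library 1. In alveolar macrophage-like cells the same list had a median of -0.0046 (adjusted p = 0.853).

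In tumour-like epithelial cells, 7 genes rose and 2 fell in the mA1 libraries among 12041 tested. Gsta1, a glutathione transferase of detoxification, rose from 2.94 ± 0.287 to 43.6 ± 2.17 CPM (SD, n = 2; log2 fold change 3.87 ± 0.22, SE; adjusted p = 0.00126). Aldh3a1, an aldehyde dehydrogenase, rose from 0.896 to 12.9 CPM (3.81 ± 0.40; adjusted p = 0.0218). The interferon-induced antiviral genes Ifit1 and Rsad2 rose by log2 values of 3.11 ± 0.30 (adjusted p = 0.0163) and 4.30 ± 0.51 (adjusted p = 0.0383). Msln, which encodes the surface protein mesothelin, rose from 103 ± 12.2 to 353 ± 72.1 CPM (1.76 ± 0.20; adjusted p = 0.0301). Cdh13, a membrane-anchored cadherin, had a log2 fold change of 2.28 ± 0.22 (adjusted p = 0.0163), and Fbln2, a matrix fibulin, one of 2.46 ± 0.28 (adjusted p = 0.0301).

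The tetraspanin gene Tspan12 fell from 53.2 ± 3.57 to 7.45 ± 1.30 CPM (log2 fold change -2.85 ± 0.20; adjusted p = 0.00367). Hbb-bs, a beta-globin chain of red blood cells, fell from 24.3 ± 5.02 to 1.68 ± 0.280 CPM (-3.86 ± 0.29; adjusted p = 0.0040). All 9 genes parted the 2 groups of 2 libraries without overlap, which chance gives for 33.3% of genes. Gsta1, Aldh3a1, Cdh13, Fbln2 and Tspan12 were named after their values were seen. Gsta1 and Hbb-bs have near-identical paralogs (Gsta2, Hbb-bt) between which counting could split or lose UMIs, so their sizes are uncertain. Gsta1 was at -0.99 when AT2-like cells and cluster 31 were counted with the epithelial class, the latter being 15 cells, 14 of them from Con library 2, with Gsta1 among its leading genes. With these clusters merged, 7 genes were called, and only 5 of them were among the 9. Just short of the threshold were Rgcc (-1.42, adjusted p = 0.0545), a cell cycle regulator, Vil1 (-2.01, 0.0545), which encodes villin of the brush border, Nup62cl (-3.90, 0.0545), the carbonyl reductase gene Cbr3 (1.76, 0.0546) and Bex4 (-1.83, 0.0609). The count rested on few libraries: it was 47 without Con library 1, 38 without Con library 2, 2 without mA1 library 1 and 0 without mA1 library 2 (880 genes at an unadjusted p under 0.05, against 967 with all libraries), and DESeq2 gave 81. The balance of directions was not stable either, with 36 up and 45 down by DESeq2, 157 and 192 without the low-count filter, 23 and 24 without Con library 1, and 12 and 26 without Con library 2. With hashtags called at 80% of counts and tumours as samples, 1 gene was called and none of these 9, with Tspan12 at -2.41 (adjusted p = 0.259), Cdh13 at 1.72 (0.202), Msln at 0.78 (0.763) and Fbln2 at 0.64 (0.935).

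**Figure D2:**
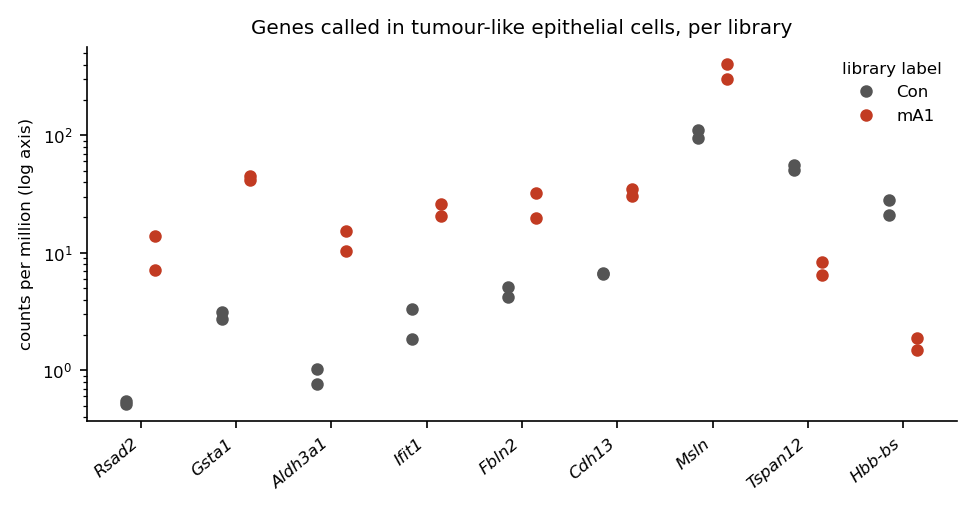
CPM of the 9 genes that passed the test in tumour-like epithelial cells, on a log scale. Each point is 1 library, and 7 genes are higher and 2 lower in both mA1 libraries.

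Among the chemokine, cytokine and checkpoint genes fixed for this comparison, none passed in epithelial cells. The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 had log2 fold changes of 0.89 ± 0.29 (49.1 to 92.3 CPM; adjusted p = 0.528) and 0.53 ± 0.24 (0.627). Leaving out 1 library gave 0.57 to 1.24 for Cxcl1 and 0.26 to 0.83 for Cxcl2, and Cxcl2 turned to -0.50 with hashtags called at 80% of counts (adjusted p = 0.932). Spp1, which encodes the secreted phosphoprotein osteopontin, had -1.31 ± 0.36 (2526 to 1026 CPM; adjusted p = 0.50), with -0.72 without Con library 2 (0.537) and -1.75 without Con library 1 (0.04995), and it passed by DESeq2 (-1.32, adjusted p = 0.00216). Il1b (-0.53, adjusted p = 0.908), Tnf (0.15, 0.946), Arg1 (-0.88, 0.889) and Cd274, which encodes PD-L1 (-0.32, 0.927), did not pass. The signs of these 4 turned without Con library 1 (Il1b 0.89, Tnf -0.32, Arg1 0.08, Cd274 0.72), and those of Tnf (-0.13) and Arg1 (0.13) without mA1 library 2. Ccl2, Ccl7 and Ccr2 had too few counts to be tested.

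The interferon response had the smallest p among the lists in epithelial cells. Of 21 measured members, 2 rose over all genes (Ifit1 and Rsad2), 8 rose when adjusted over the list alone, and 20 had a positive log2 fold change (median 0.94). Ifit3 (2.75, adjusted p = 0.0695), the guanylate-binding protein gene Gbp2 (2.19, 0.208), the transcription factor gene Irf7 (1.05, 0.294) and the ubiquitin-like modifier gene Isg15 (0.94, 0.504) did not pass singly. camera gave an adjusted p = 3.14e-10 for the list, which was lost with an estimated correlation (adjusted p = 0.675). Genes of MHC class I antigen presentation moved the same way. None of 11 passed over all genes, 5 rose over the list alone, and 10 were positive (median 0.58; camera adjusted p = 3.53e-06, and adjusted p = 0.815 with an estimated correlation). Examples are the immunoproteasome subunit gene Psmb8 (1.20, adjusted p = 0.124), the tapasin gene Tapbp (0.72, 0.293), B2m (0.61, 0.469) and H2-Q7 (1.24, 0.338), the last of which shares sequence with other H2 genes. In alveolar macrophage-like cells neither list passed, with medians of -0.06 for interferon response (adjusted p = 0.80) and -0.0048 for MHC class I (adjusted p = 0.937, where the test's direction was up and the mean -0.02).

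A further 4 epithelial lists passed camera and lost that call with an estimated correlation. The Malat1 neighbours are one of them, and each of the other 3 had 0 members passing over all genes. Of 18 NF-kB response genes 15 were positive and 1, the signalling adaptor gene Traf1 (0.83, adjusted p = 0.244), rose over the list alone (median 0.26; camera adjusted p = 0.00603, with an estimated correlation adjusted p = 0.815). Of 13 mitochondrial genes 12 were positive (median 0.25; adjusted p = 0.00252, with an estimated correlation 0.815). Of 24 dissociation and immediate early genes 19 were negative and 1 fell over the list alone, Fos, a transcription factor gene induced within minutes (-0.98 ± 0.21, adjusted p = 0.214). This list was lower by camera (median -0.41; adjusted p = 1.66e-05, and adjusted p = 0.815 with an estimated correlation), and other members were Zfp36 (-0.81) and Klf4 (-0.70).

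Markers of other cells mostly had negative values in the epithelial cells of mA1 libraries. All 4 genes of free blood RNA had negative values (median -3.22), of which Hbb-bs fell over all genes and all 4 over the list alone. Free plasma cell RNA had 4 negative of 4 measured (median -1.98, 1 fell over the list alone), and free myeloid RNA 5 negative of 6 (median -0.90, adjusted p = 0.151). Free AT2 RNA was split evenly (median -0.20, adjusted p = 0.337).

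In the remaining lists no member passed over all genes in epithelial cells, and no list passed. Chemokines had a median of 0.44 (adjusted p = 0.0811), with 5 of 16 rising over the list alone, among them Cxcl16 (0.81, adjusted p = 0.177) and Cxcl17 (0.82, 0.312), and 1 falling, Ccl5 (-0.90, 0.312). Inflammatory cytokines had 13 positive of 16 (median 0.17, adjusted p = 0.153, with Il18 at 1.27 rising over the list alone), cell cycle genes 19 of 23 (0.29, 0.353), EMT and invasion 12 of 17 (0.17, 0.427, 1 falling over the list alone) and neutrophil activation 7 of 12 (0.06, 0.821). AT2 identity genes were divided, 8 up and 10 down (median -0.20, adjusted p = 0.336), with Nkx2-1, the lineage factor, at -0.51 (0.516) and the surfactant genes Sftpb and Sftpc at -0.78 and -0.43. Tumour progression states had 11 positive of 20 (median 0.09, adjusted p = 0.784), with 2 falling over the list alone, and held the gastric genes Gkn2 (-2.66, 0.209) and Tff1 (2.11, 0.428). Lipid-associated macrophage genes (12 negative of 18, median -0.19, adjusted p = 0.0787), alternative macrophage genes (5 of 7, -0.25, 0.0927), T cell cytotoxicity genes (3 of 5, -0.90, 0.0927) and inflammatory macrophage genes (3 of 7, median 0.11, 0.950) each had 1 member falling over the list alone, Apoc1 (-2.27), Pparg (-1.03) and, in the last 2 lists, Ccl5.

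Monocyte recruitment receptors (7 negative of 8, median -0.55, adjusted p = 0.151), MHC class II (6 of 7, -0.11, 0.186), immune checkpoints (6 of 8, -0.11, 0.821), T cell exhaustion (4 of 5, -0.26, 0.598), regulatory T cell (4 of 5, -0.30, 0.821) and nuclear long RNAs (5 of 8, -0.11, 0.427) had no member passing on either scale in epithelial cells. Splicing factors (14 of 26 negative, median -0.01, adjusted p = 0.336) and ribosomal proteins (13 of 21, -0.06, 0.427) stayed near 0. The matrix and fibroblast activation list had 1 member rising and 1 falling over the list alone (median -0.15, adjusted p = 0.498). Naive T cell genes, with 4 measured, were too few to test (median -0.72). For hypoxia and glycolysis (12 positive of 19, median 0.02, adjusted p = 0.821) and p53 targets (6 of 12, 0.03, 0.961) the test pointed down although median and mean were positive, and for endothelial activation (3 of 5, 0.05, 0.598, 1 falling over the list alone) median and mean (-0.16) differed in sign.

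Sub-clustering of the epithelial cells gave 9 states, of which states 2 and 8 were larger and state 3 smaller in both mA1 libraries than in both Con libraries. State 2, led by Cxcl3, Ly6a, Homer2 and Cxcl1, made up 14.5% and 14.1% of epithelial cells in the Con libraries and 40.8% and 54.0% in the mA1 libraries (14.3 ± 0.293% against 47.4 ± 9.33%, SD, n = 2). Groups of 2 part in this way in 33.3% of arrangements, and the exact two-sided permutation p was 0.333, the smallest possible (adjusted p = 1). Msln, which passed the test between groups, is among its leading genes, so the cells were clustered again without the 9 called genes. The state then held 96.3% of its earlier cells and 13.5 ± 0.898% against 46.0 ± 8.25% (exact p = 0.333). State 8, led by the proliferation genes Top2a, Mki67 and Birc5 and by the called gene Fbln2, kept all 26 of its cells in that clustering, at 1.79% and 5.30% (exact p = 0.333). State 3 was less stable there and kept 67.5% of its earlier cells.

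Some epithelial states came mostly from 1 library. State 5, led by the apolipoprotein genes Apoc2 and Apoe and the gastric gene Gkn2, had 79 of its 83 cells in Con library 2, and state 6, led by the stress gene Chac1 with Spp1 and Rgcc, had 66 of 75 in Con library 1. State 3, with Igfbp3 and the chromatin protein gene Hmga2, made up 25.9% of the epithelial cells of Con library 1 and 4.91%, 4.46% and 2.16% in Con library 2 and the mA1 libraries. State 1, with A2ml1 and Acta2, ran at 33.7% and 9.82% against 17.8% and 17.3%, and state 4, with the antigen presentation genes Cd74 and H2-Aa, at 7.26% and 18.4% against 23.6% and 13.7%. States 7 (Chil3, Lyz2) and 9 (Ccl5, Gzma, Nkg7) were led by genes of macrophages and lymphocytes, and stayed unnamed. They held 30 and 11 cells, of which 19 and 7 came from Con library 1. These cells stayed in the epithelial sums, so epithelial values of immune genes include their UMIs. No alternative left out these 2 states as such.

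**Figure D3:**
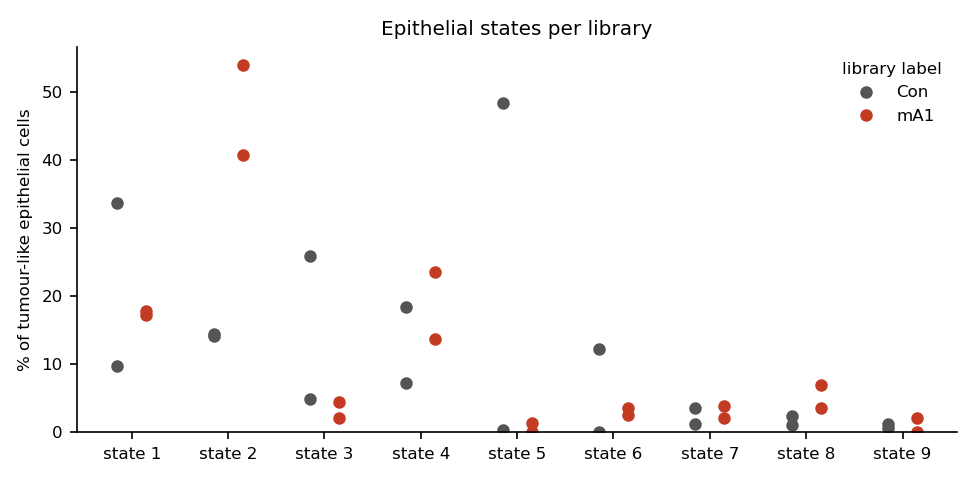
Percent of tumour-like epithelial cells of each library in states 1 to 9. Each point is 1 library; state 2 is higher in both mA1 libraries than in both Con libraries.

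Alveolar macrophage-like cells, the largest immune class, showed 2 gene changes among 11247 tested, and both are epithelial genes. Sftpb, which encodes surfactant protein B of alveolar type 2 cells, fell from 11.9 ± 2.23 to 3.96 ± 0.534 CPM in the mA1 tumours (SD, n = 4; log2 fold change -1.57 ± 0.17, SE; adjusted p = 0.0132). Krt18, a keratin of simple epithelia and named after its value was seen, fell from 6.94 to 2.55 CPM (-1.40 ± 0.18; adjusted p = 0.0341). Of the 5 next genes by p, which did not pass, 3 are typical of epithelia as well, Wfdc2 (-1.23, adjusted p = 0.0596), Krt8 (-1.41, 0.0602) and S100a14 (-1.62, 0.0770), and 1 encodes a small heat shock protein, Hspb1 (-2.0, 0.0596). The fifth, Phgdh, the first enzyme of serine synthesis, went from 237 to 292 CPM (0.33 ± 0.05, adjusted p = 0.0770).

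Inflammatory genes of these macrophages did not pass. Il1b had 93.9 ± 17.7 CPM in Con and 54.5 ± 10.5 in mA1 tumours (log2 fold change -0.76 ± 0.16, n = 4; adjusted p = 0.277), without overlap between the groups. Chance gives this for 2.86% of genes if tumours are exchangeable. With group means removed, tumours of 1 library correlated at 0.114 in this class, against -0.554 between libraries of a group, so chance can give it more often. With libraries as replicates Il1b was at -0.83 (edgeR adjusted p = 0.9997). The monocyte chemokine gene Ccl2 (-0.66 ± 0.38, adjusted p = 0.679) and its receptor gene Ccr2 (-0.74 ± 0.29, 0.544) had negative values. Near 0 were Cxcl2 (-0.10, adjusted p = 0.980), Tnf (-0.13, 0.878), Spp1 (-0.11, 0.857), Cd274 (-0.07, 0.892) and Neat1 (-0.05, 0.923). Cxcl1 (-0.31, 0.937) and Arg1 (0.65, 0.921) varied between tumours, and leaving out single tumours gave Arg1 between -1.92 and 1.03. Ccl7 was not measured.

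The 2 calls of alveolar macrophage-like cells depended on the samples used. They were lost (0 called) without mA1 library 1 hashtag 1, without mA1 library 1 hashtag 2, without mA1 library 2 hashtag 2, and with libraries as replicates (328 genes at an unadjusted p under 0.05 against 942 with tumours), and 6 genes were called without Con library 1 hashtag 2. DESeq2 called 42, and 6 were called without the Xist-expressing Con library, of which 1 was among the 2 (Sftpb at -1.74, adjusted p = 0.0123, against Krt18 at -1.45, 0.0550). The log2 fold changes themselves moved little, from -1.64 to -1.39 for Sftpb and -1.50 to -1.31 for Krt18 with 1 tumour left out, and -1.58 and -1.39 with libraries as replicates (adjusted p = 0.788 each).

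Of the gene lists, 3 were higher and 8 lower by camera in alveolar macrophage-like cells, and none kept its call with an estimated correlation. All 8 MHC class II genes were positive (median 0.23, among them Cd74 at 0.29 and H2-Ab1 at 0.29), and so were 21 of 21 ribosomal protein genes (median 0.13) and 14 of 17 lipid-associated macrophage genes (median 0.08, with the lipid carrier gene Fabp5 at 0.38), though no member of these lists passed on either scale. Their adjusted p were 0.00572, 3.12e-07 and 0.0179, and with an estimated correlation adjusted p = 0.617, 0.548 and 0.695. The ribosomal median was -0.0033 without the Xist-expressing Con library. Lower were neutrophil activation (13 of 13 negative, median -0.25, 4 falling over the list alone, among them Il1b and the granule gene Retnlg at -1.84) with an adjusted p of 1.83e-06, and immediate early genes (20 of 23, median -0.25, Fos at -0.32) with 5.82e-06. The immediate early median was -0.14 without the Xist-expressing Con library. The free myeloid RNA list had 4 negative of 6 in these cells (median -0.56, adjusted p = 0.262). Neutrophil activation and immediate early genes each had an adjusted p = 0.101 with an estimated correlation and 0.0498 by fry. Monocyte recruitment receptors had 8 negative of 11 (median -0.25; adjusted p = 0.00572, with an estimated correlation adjusted p = 0.245).

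A further 5 lower lists of alveolar macrophage-like cells hold genes of other cells, while free blood RNA went the other way (4 of 4 positive, median 0.78). Free plasma cell RNA had 5 negative of 5, 4 of which fell over the list alone (median -1.17, with the antibody genes Igha at -1.29, Igkc at -1.17 and Jchain at -1.17; adjusted p = 3.12e-07). Free AT2 RNA had 5 negative of 6 (median -0.86, Sftpa1 at -1.20; adjusted p = 7.49e-06), and AT2 identity 9 of 12 (median -0.44; adjusted p = 3.21e-04). In each of these 2 lists, Sftpb fell over all genes and 3 members fell over the list alone. Tumour progression states had 7 negative of 8 (median -0.60, Krt7 at -0.99; adjusted p = 0.00233) and matrix and fibroblast activation 5 of 5 (median -0.91; adjusted p = 0.00265), with 3 and 2 falling over the list alone. With an estimated correlation the adjusted p were 0.101, 0.101, 0.173, 0.101 and 0.164. Lists of inflammation did not pass: chemokines (median -0.27, adjusted p = 0.127), inflammatory cytokines (-0.13, 0.122), NF-kB response (-0.11, 0.0835), inflammatory macrophage (-0.19, 0.227) and alternative macrophage genes (0.07, 0.901).

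The smaller macrophage classes gave few calls. Macrophage cluster 6, led by Inhba, Mmp12 and Ccl9, had 2 falls among 8747 genes, Sftpb (-1.58, adjusted p = 0.0336) and Krt18 (-2.18, adjusted p = 0.0375). Each kept its call in 1 of the 8 fits that leave out 1 tumour, and the count ran from 0 to 6. The 6 genes called without mA1 library 1 hashtag 2 held neither of them. In this class 11 of 13 interferon response genes were negative (median -0.37; camera adjusted p = 3.14e-04, with an estimated correlation adjusted p = 0.299). All 8 MHC class II genes were positive (median 0.37; adjusted p = 8.13e-06, with an estimated correlation 0.299), and monocyte recruitment receptors were lower (median -0.35; adjusted p = 6.02e-05, with an estimated correlation 0.0683). Markers of other cells were lower too: AT2 identity (7 of 8 negative, median -0.40; adjusted p = 1.83e-05, with an estimated correlation 0.0683), free myeloid RNA (6 of 6, median -0.94; adjusted p = 0.00548, with an estimated correlation 0.299), free plasma cell RNA (3 of 3, median -1.23) and free AT2 RNA (3 of 3, median -0.93). Immediate early genes were also lower (median -0.18; adjusted p = 5.16e-04, with an estimated correlation 0.588). C1q macrophage-like cells had 0 calls by edgeR among 6131 genes (241 at an unadjusted p under 0.05) and 0 by DESeq2, with MHC class II again positive (median 0.18; adjusted p = 0.0124, with an estimated correlation 0.861). Whether these effects differ from those of alveolar macrophage-like cells was not tested.

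In NK-like cells 5 genes rose and 12 fell among 5999. The chemokine gene Ccl3 fell from 438 ± 55.9 to 243 ± 5.45 CPM (SD, n = 4; log2 fold change -0.85 ± 0.12, SE; adjusted p = 1.02e-06). The immediate early genes Fos (-0.82, adjusted p = 3.67e-05), Egr1 (-1.12, 0.00329), Btg2 (-0.52, 0.0159) and the phosphatase gene Dusp2 (-0.70, 0.0353) fell, as did Tob1, an antiproliferative gene (-1.21, 0.0219), and Klra1, which encodes an inhibitory NK receptor (-0.84, 1.16e-04). Higher were Cd27, a receptor of less mature NK cells (49.6 to 90.9 CPM; 0.91 ± 0.19; adjusted p = 0.0081), the adhesion receptor gene Crtam (1.86, 0.0208), Serpina3g (0.88, 0.0278), Ltb (1.05) and Cxxc5 (0.95). The smallest p was that of Clu, a secreted chaperone abundant in the epithelial cells, which fell from 83.3 to 18.4 CPM (-2.23 ± 0.26; adjusted p = 1.04e-08), and the plasma cell gene Igha fell too (-1.04, 1.12e-04). The granzyme genes Gzma (-0.10, adjusted p = 0.770) and Gzmb (-0.27, 0.416) did not pass. Clu, Igha, Ccl3, Fos and Klra1 kept their calls in all 8 fits that leave out 1 tumour, while the count ran from 5 without mA1 library 1 hashtag 2 to 36 without Con library 1 hashtag 2, with 7 and 9 without the tumours of Con library 2 and 28 without Con library 1 hashtag 1. The other calls held less well. Among the rises, Cd27 kept its call in 6 of the 8 fits, Serpina3g, Ltb and Cxxc5 in 3 and Crtam in 1. Among the other falls named here, Egr1 kept its call in 5, Btg2 in 4, and Tob1 and Dusp2 in 3. No gene rose (0) without Con library 2 hashtag 1, without mA1 library 1 hashtag 2, without the Xist-expressing Con library, by DESeq2, with equal cell numbers or with libraries as replicates. With libraries as replicates 4 genes were called, 3 of them among the 17: Clu, Igha (adjusted p = 0.0171) and Ccl3 (0.0171) passed, and Fos (0.0762), Cd27 (0.0790), Egr1 (0.0837) and Klra1 (0.115) did not. Without the Xist-expressing Con library 5 of the 17 were called, with Clu at -1.70 (adjusted p = 0.00259), Fos at -0.69 (0.0218), Klra1 at -0.66 (0.238) and Cd27 at 0.72 (0.598). Klra1 belongs to a family of similar receptors, so counting could shift UMIs among them. Fos, Btg2, Dusp2, Klra1, Crtam, Serpina3g, Ltb and Cxxc5 were named after their values were seen.

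As lists, the immediate early genes of NK-like cells were lower in 18 of 18 members (median -0.37, 3 falling over all genes and 5 over the list alone; camera adjusted p = 1.16e-11, with an estimated correlation adjusted p = 0.210). Chemokines (median -0.34; adjusted p = 5.77e-04) and neutrophil activation genes (median -0.31; adjusted p = 8.05e-04) were lower and ribosomal proteins higher (median 0.17; adjusted p = 2.05e-10), with an estimated correlation adjusted p = 0.240, 0.240 and 0.281. Without the Xist-expressing Con library the ribosomal median was 0.02.

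CD8 T-like cells had 1 rise and 9 falls among 6345 genes. Kxd1, part of a lysosome-positioning complex, rose (0.74, adjusted p = 0.0228), and Zeb2, a transcription factor of terminal effector cells (-0.81, 0.0228), the RNA-decay gene Zfp36 (-0.74, 0.0354), Mob1a (-0.73), Atxn2l (-0.89, 0.0143), Reps1 (-1.12, 0.0354) and Clu (-1.68, 3.94e-04) fell. The effector marker Cx3cr1 was at -1.01 (adjusted p = 0.0780). The CD8 count ran from 2 to 141 as tumours were left out, the highest without Con library 1 hashtag 2. In that fit 95 genes rose and 46 fell, so the balance of directions was not stable. In CD4 T-like cells the B cell genes Cd79a (-2.49, adjusted p = 7.44e-05) and Ebf1 (-2.68, 0.0109) and Clu (-1.63, 0.0435) fell among 7605 genes, and 0 were called with Scrublet doublets kept or with more doublets left out. Reps1, Cd79a and Ebf1, and the 2 genes of macrophage cluster 6, were named after their values were seen. B cell-like cells had 1 fall among 6533 genes, Clu (66.0 ± 16.9 to 16.5 ± 8.05 CPM; -1.75 ± 0.24; adjusted p = 4.94e-04), and up to 15 without mA1 library 2 hashtag 2. Gamma-delta T-like cells had 2 falls among 4339 genes, Igha (-1.46, adjusted p = 0.0106) and the selenium transport gene Selenop (-0.69, 0.0326), 0 without mA1 library 1 hashtag 2 and 6 without Con library 1 hashtag 1.

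None of these calls in CD8 T-like, CD4 T-like, B cell-like and gamma-delta T-like cells held without the Xist-expressing Con library, which leaves 2 Con tumours. Clu was then at -1.06 in CD8 T-like (adjusted p = 0.592), -1.14 in CD4 T-like (0.0665) and -1.51 in B cell-like cells (0.179), Cd79a at -2.35 (0.0511) and Ebf1 at -2.93 (0.0665) in CD4 T-like cells, and Igha at -1.39 in gamma-delta T-like cells (0.0566). With libraries as replicates, 0 genes were called in CD8 T-like, 0 in B cell-like, 0 in gamma-delta T-like and 1 in CD4 T-like cells.

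Neutrophil-like and cDC2-like cells had 0 calls by edgeR, among 3816 and 6163 genes (104 and 218 at an unadjusted p under 0.05, and 1 each by DESeq2). The genes with small p included Clu in both (-1.52, adjusted p = 0.726, and -1.82, 0.818), and the stress phosphatase gene Dusp1 in cDC2-like cells (-0.63, 0.221). Across classes, Clu had values between -1.52 and -2.23 in 9 immune classes and 0.04 in the tumour-like epithelial cells themselves. Ribosomal protein genes were higher by camera in 8 immune classes and lower in neutrophil-like cells (median -0.14, adjusted p = 0.0374, with an estimated correlation 0.752). In the 8 classes the adjusted p with an estimated correlation ran from 0.281 to 0.861. Without the Xist-expressing Con library the medians were -0.0033 in alveolar macrophage-like, 0.07 in cluster 6, 0.13 in C1q macrophage-like, 0.09 in B cell-like, 0.02 in NK-like, 0.02 in CD4 T-like, 0.13 in CD8 T-like and 0.06 in gamma-delta T-like cells, and -0.40 in neutrophil-like cells.

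**Figure D4:**
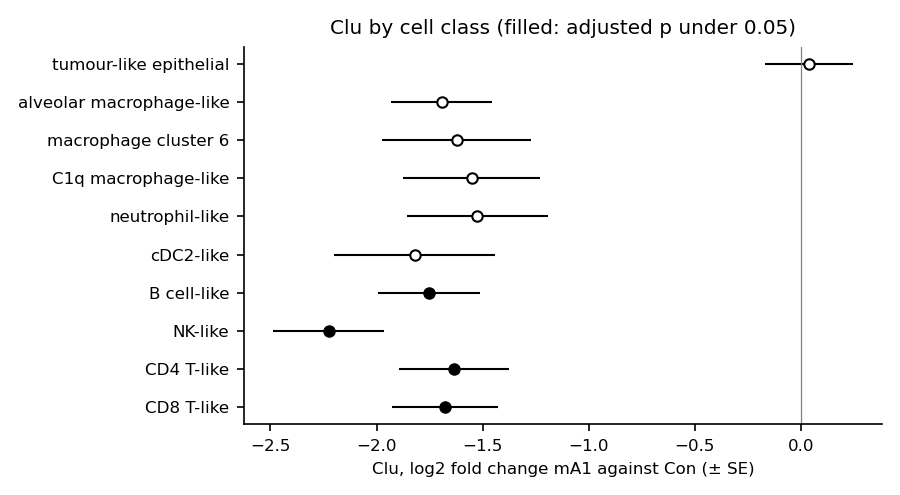
Log2 fold change of Clu with its standard error in 10 classes, mA1 against Con. Filled points mark an adjusted p under 0.05, reached in B cell-like, NK-like, CD4 T-like and CD8 T-like cells.

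After correction over 14 classes, no class passed the test of its share of cells. The test takes the 8 tumours as exchangeable, although each library holds 2 of them. With the 4 libraries as units the smallest possible exact p is 0.333. Alveolar macrophage-like cells made up 21.2 ± 8.61% of cells in Con and 34.8 ± 8.10% in mA1 tumours (mean ± SD, n = 4; exact two-sided permutation p = 0.0857, adjusted p = 0.400), with ranges of 13.2 to 32.8% and 27.4 to 44.9%. cDC1-like cells, which cross-present antigen, were at 1.31 ± 0.188% and 0.838 ± 0.126% without overlap (exact p = 0.0286, the smallest possible, adjusted p = 0.400). Plasma cell-like cells were at 1.78 ± 0.371% and 0.836 ± 0.414% (exact p = 0.0571), C1q macrophage-like cells at 3.5 ± 1.81% and 1.72 ± 0.546% (exact p = 0.143) and NK-like cells at 10.5 ± 4.50% and 6.24 ± 1.87% (exact p = 0.171). Without the Xist-expressing Con library, the difference for NK-like cells was -0.553 points, that for C1q macrophage-like cells -3.12 and that for alveolar macrophage-like cells 7.14. With 1 tumour left out, it ran from -2.53 to -1.11 points for C1q macrophage-like and -5.77 to -2.60 for NK-like cells. Mean shares of the others were 1.44% and 1.52% for monocyte-like, 8.55% and 9.36% for neutrophil-like, 5.62% and 5.02% for macrophage cluster 6, 2.47% and 2.17% for cDC2-like, 0.860% and 0.996% for mature DC-like, 10.1% and 11.6% for B cell-like, 15.2% and 12.7% for CD4 T-like, 9.43% and 6.99% for CD8 T-like, and 3.92% and 3.02% for gamma-delta T-like cells. Without the Xist-expressing Con library, differences turned to 2.65 points for CD4 T-like, 1.52 for CD8 T-like, -1.71 for neutrophil-like, -0.162 for monocyte-like and -0.0520 for mature DC-like cells. Macrophage cluster 6 and B cell-like cells kept their direction, with larger differences. Cluster 6 made up 5.72% and 10.5% of the tumours of Con library 1, against 1.77% and 4.51% in Con library 2. For B cell-like cells these shares were 7.76% and 9.06%, against 13.7% and 9.98%. The shares are of recovered cells with 1 hashtag. That was 73.0% of C1q macrophage-like cells, against 86.6% (monocyte-like) to 98.8% (CD8 T-like) in the other classes compared here. In tumour-like epithelial, mast or basophil-like and AT2-like cells it was 18.6%, 11.7% and 62.6%. Over all cells of a library, C1q macrophage-like cells numbered 379 of 7108 and 123 of 5663 in Con libraries. In mA1 libraries they numbered 176 of 7406 and 114 of 3797, and these proportions overlap. Tumours held a smaller part of them in the mA1 libraries.

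**Figure D5:**
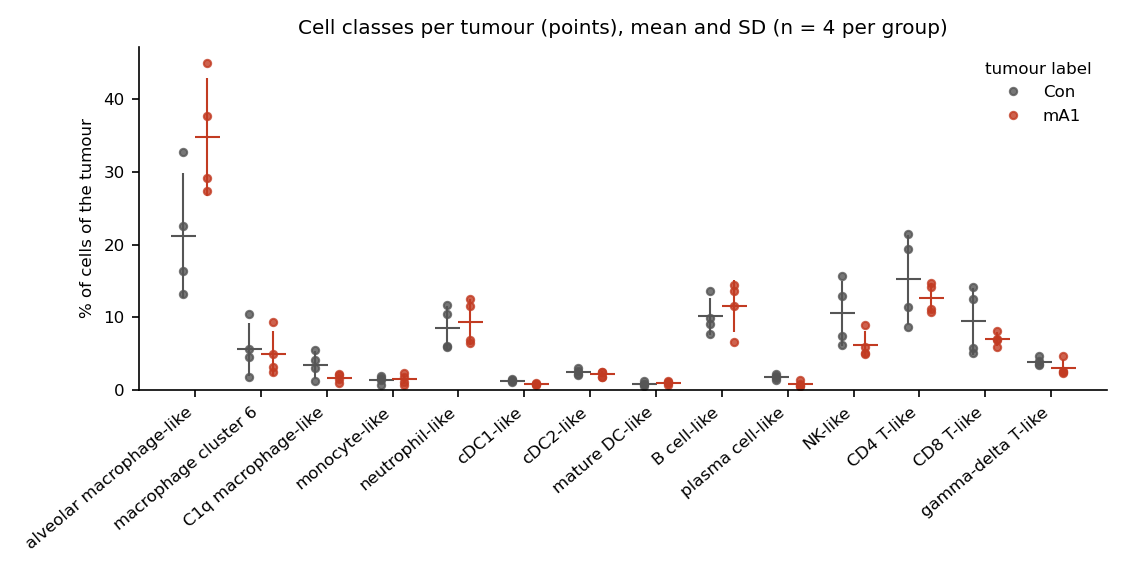
Percent of the cells of each tumour in 14 classes. Points are tumours, with group mean and SD (n = 4), and no class passed after correction.

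Classes that carried few hashtags were compared per library, with n = 2. These shares are of all kept cells of a library, among them the unnamed cluster 15. It made up 3.04% and 4.92% of the mA1 and 0.577% and 0.795% of the Con libraries, which lowers the mA1 shares. Tumour-like epithelial cells made up 5.22 ± 3.31% of cells in Con and 2.89 ± 1.09% in mA1 libraries (exact p = 0.667), a difference that was 0.0120 points without Con library 1 and -4.66 without Con library 2. Mast or basophil-like cells were at 0.826 ± 0.244% and 0.314 ± 0.0716%, fibroblast-like cells at 0.523% and 0.388%, and endothelial-like cells at 0.0950% and 0.200% (exact p = 0.333 each, the smallest possible). Within the monocytes and macrophages, 12 states were found. State 5, led by Apoe and the complement genes C1qa, C1qb and C1qc, made up 9.81 ± 2.90% in Con and 3.54 ± 1.23% in mA1 tumours without overlap (exact p = 0.0286, adjusted p = 0.343). Of the 342 and 113 state 5 cells of the Con libraries, tumours held 75 and 212, and 35 and 51. Of the 150 and 97 of the mA1 libraries, tumours held 20 and 81, and 20 and 30. A smaller part was thus assigned in the mA1 libraries, so hashtag yield adds to this difference. State 1, with the lipid genes Fabp4 and Gpnmb, was at 25.4 ± 16.5% and 41.0 ± 4.32% (exact p = 0.171), a difference that was 1.78 points without the Xist-expressing Con library (39.2% in the other Con tumours). State 3, with Cxcl2, Hilpda and Areg, was at 14.1% and 11.7%, and state 8, with the monocyte genes Plac8 and Ly6c2, at 4.00% and 3.08% (exact p = 0.4). State 6, with Ccl17 and Isg15, had 5.76% and 4.51%, and the proliferating state 4 had 10.1% and 10.9%.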

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

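Of the tests in this part, the comparison of cluster 15 with the hashtag background was chosen only after the result was seen. Within groups of 4 tumours, gamma-delta T-like cells of mA1 library 1 hashtag 1 made up 4.73% of cells, apart from 2.30 to 2.58% in the other 3 mA1 tumours. It was the 1 sample to stand out among 72 groups examined, and chance flags about 1 in 20 groups.

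Cluster 15 was not itself compared between groups, but its barcodes count among the cells that the shares per library are taken of. They had almost no hashtag counts (434 of 498 had 0) and few UMIs (medians of 535 to 591 per library). It made up 3.98% of cells on average in the mA1 libraries (3.04% and 4.92%), against 0.577% and 0.795% in the Con libraries, and was led by Ttr, Enpp2, Ecrg4 and Folr1, genes known from the choroid plexus rather than the lung. Cells of the tumour suspension that failed to bind the antibodies were argued against, because 3.41% of the barcodes (17 of 498) reached the hashtag background of 78 counts seen in epithelial cells without a hashtag. Reads carried over between libraries may account for most of the cluster: 85.9% of its barcodes (428 of 498) were cluster 15 barcodes in another library too, against 0.952% of the other 23107 barcodes. Each library of the series held the cluster at low median UMIs, so no source library was seen among them. The sharing cannot tell whether the reads came from inside the series. What stays open is the origin of the RNA, and no biological explanation was tested.

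In cluster 17, the barcodes without hashtag counts were all (100%) present in another library as well, a value not weighed further.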

How the results depend on the processing

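Of the alternatives below, those that leave out top-scoring doublets or the Xist-expressing Con library, merge clusters, use a crossed block, take cells with at least 10 hashtag counts, or leave the called genes out of the epithelial clustering were chosen only after the results were seen, as was the 80% hashtag rule for Malat1 against other classes. Named genes kept direction and side of the threshold in 1089 comparisons with other settings, passed newly in 102, no longer passed in 170 and turned in 10. Counts of called genes stayed within 1.5 times in 75 comparisons and moved further in 57, counts of lists in 13 and 30, and shares kept direction in 238 and turned in 8. Except where fewer samples or genes enter, the cause of these moves was not tested.

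With all settings as reported, the called genes numbered 9 in tumour-like epithelial, 2 in alveolar macrophage-like, 2 in macrophage cluster 6, 0 in C1q macrophage-like, 0 in neutrophil-like, 0 in cDC2-like, 1 in B cell-like, 17 in NK-like, 3 in CD4 T-like, 10 in CD8 T-like and 2 in gamma-delta T-like cells. DESeq2 called 81 in epithelial, 42 in alveolar macrophage-like, 8 in cluster 6, 1 in neutrophil-like, 1 in cDC2-like, 5 in NK-like, 8 in CD4 T-like and 2 in CD8 T-like cells. Without the low-count filter the numbers were 349 in epithelial, 18 in alveolar macrophage-like, 11 in cluster 6, 6 in C1q macrophage-like, 5 in neutrophil-like, 8 in cDC2-like, 29 in B cell-like, 34 in NK-like, 41 in CD4 T-like, 28 in CD8 T-like and 14 in gamma-delta T-like cells.

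Keeping Scrublet doublets gave 5 in alveolar macrophage-like and 0 in CD4 T-like cells. Leaving out top-scoring doublets gave 0 in CD4 T-like and 4 in gamma-delta T-like cells, and turned the log2 values of Malat1 in C1q macrophage-like (0.058) and cDC2-like cells (0.0059) and of Cxcl2 (0.32) and Tnf (0.016) in alveolar macrophage-like cells. Stricter cells gave 1 gene in alveolar macrophage-like cells and Malat1 at 0.0068 in cDC2-like cells. Equal cell numbers gave 0 in alveolar macrophage-like, 5 in cluster 6, 3 in B cell-like, 1 in NK-like, 7 in CD4 T-like, 0 in CD8 T-like and 0 in gamma-delta T-like cells, and Malat1 at 0.11 in cDC2-like cells. The 80% hashtag rule gave 1 gene in epithelial cells, none of the 9 reported, and 1 in alveolar macrophage-like cells, Malat1 at 0.062 in C1q macrophage-like cells, and Cxcl2 at -0.50 and Tnf at -0.35 in epithelial cells. With neighbouring clusters merged, Gsta1 was at -0.99, Arg1 at 0.00030 and Tnf at -0.20 in epithelial cells, so the rise of Gsta1 holds for the class without the AT2-like cells and without cluster 31, which Gsta1 helps to lead.

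With libraries as replicates, 0 genes were called in alveolar macrophage-like, 0 in cluster 6, 1 in neutrophil-like, 0 in B cell-like, 4 in NK-like, 1 in CD4 T-like, 0 in CD8 T-like and 0 in gamma-delta T-like cells, and 18 lists in alveolar macrophage-like, 5 in C1q macrophage-like and 4 in CD8 T-like cells, with Malat1 at 0.0020 in CD8 T-like cells. A random effect of library gave 0 in alveolar macrophage-like, 1 in cluster 6, 9 in NK-like, 4 in CD8 T-like and 0 in gamma-delta T-like cells, and Arg1 at -1.06 in alveolar macrophage-like cells. A replicate block by library number gave 40 genes in epithelial, 12 in alveolar macrophage-like, 10 in CD4 T-like and 4 in gamma-delta T-like cells, and 10 lists in epithelial, 4 in C1q macrophage-like, 1 in neutrophil-like, 7 in CD4 T-like and 6 in CD8 T-like cells. The labels do not say that equal library numbers were handled together, and with group means removed the libraries of equal number correlated at -0.115 in neutrophil-like, -0.081 in epithelial and at most 0.112 (B cell-like) in the other classes. A crossed block called 1 gene in neutrophil-like cells. Permutation within blocks has 36 arrangements and a smallest exact p of 0.0556.

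Lists passing camera numbered 6 in epithelial, 11 in alveolar macrophage-like, 8 in cluster 6, 2 in C1q macrophage-like, 3 in neutrophil-like, 2 in cDC2-like, 5 in B cell-like, 4 in NK-like, 4 in CD4 T-like, 2 in CD8 T-like and 5 in gamma-delta T-like cells. With an estimated correlation each of these numbers was 0. Because that version was not checked on simulated lists, a call lost there does not show that a list is unchanged. By fry it was 6 in alveolar macrophage-like, 1 in NK-like and 0 in the others.

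Without the Xist-expressing Con library, 6 genes were called in alveolar macrophage-like, 1 in C1q macrophage-like, 3 in neutrophil-like, 11 in NK-like, 8 in CD4 T-like and 2 in CD8 T-like cells. The genes shared with those reported numbered 1 in alveolar macrophage-like, 1 in cluster 6, 5 in NK-like and 0 in B cell-like, CD4 T-like, CD8 T-like and gamma-delta T-like cells. Malat1 was at 0.11 in neutrophil-like, 0.045 in cDC2-like, 0.048 in CD8 T-like and 0.094 in gamma-delta T-like cells, and Neat1 at 0.11 and Tnf at 0.017 in alveolar macrophage-like cells. Differences of shares in percentage points turned to -0.162 for monocyte-like, -1.71 for neutrophil-like, -0.0520 for mature DC-like, 2.65 for CD4 T-like and 1.52 for CD8 T-like cells, and to 11.5, 0.0520 and 0.0354 for myeloid states 2, 10 and 12.

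Leaving out each tumour (or library, for epithelial cells) gave called genes from 0 to 47 in epithelial, 0 to 6 in alveolar macrophage-like, 0 to 6 in cluster 6, 0 to 3 in neutrophil-like, 0 to 2 in cDC2-like, 1 to 15 in B cell-like, 5 to 36 in NK-like, 2 to 9 in CD4 T-like, 2 to 141 in CD8 T-like and 0 to 6 in gamma-delta T-like cells. Malat1 ranged from -0.45 to 0.48 in epithelial, -0.041 to 0.17 in alveolar macrophage-like, -0.14 to 0.11 in C1q macrophage-like, -0.17 to 0.036 in neutrophil-like, -0.10 to 0.075 in cDC2-like, -0.13 to 0.034 in NK-like, -0.079 to 0.046 in CD8 T-like and -0.15 to 0.04 in gamma-delta T-like cells, and in epithelial cells against other classes from -0.28 to 0.46. In epithelial cells, Neat1 ranged from -0.32 to 0.10, Il1b from -1.20 to 0.89, Tnf from -0.32 to 0.76, Arg1 from -6.81 to 0.13 and Cd274 from -0.87 to 0.72. In alveolar macrophage-like cells, Neat1 ranged from -0.12 to 0.015, Cxcl1 from -0.67 to 0.64, Cxcl2 from -0.35 to 0.17, Tnf from -0.24 to 0.0088, Arg1 from -1.92 to 1.03 and Cd274 from -0.16 to 0.0061.

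Differences of shares ranged from -2.03 to 1.02 points for cluster 6, -0.208 to 0.337 for monocyte-like, -0.230 to 1.88 for neutrophil-like, -4.66 to 0.0120 for epithelial and -0.782 to 0.0850 for AT2-like cells. For myeloid states 2, 3 and 12 they ranged from -12.1 to 1.29, -4.81 to 0.302 and -0.169 to 0.00556, and for epithelial states 1, 5, 6, 7 and 9 from -16.2 to 7.73, -47.7 to 0.347, -9.22 to 3.07, -0.548 to 1.76 and -0.959 to 1.20. Not run were equal cell numbers, a random effect of library and tumours by the mixture call of hashtags for epithelial cells, the 80% rule for epithelial states, and kept doublets for epithelial and myeloid states. With 1 library left in a group, shares are values without a test, and in the gene fits the lone library is assumed to vary like those of the other group.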

Other observations

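Of the tests in this part, the comparison of epithelial UMI shares with Clu and the count of classes with lower immediate early genes were chosen only after the result was seen, as were the fits without the Xist-expressing Con library. EGFP, present among the gene features, had UMIs in other classes too. At least 1 EGFP UMI was found in 23.8% of tumour-like epithelial cells (95% interval 21.2 to 26.6%), from 11.7% in Con library 1 to 57.1% in Con library 2 (mA1 libraries 19.1% and 36.7%). It was also found in 16.5% of AT2-like cells, 7.43% of alveolar macrophage-like cells (6.76 to 8.16%) and 7.07% of macrophage cluster 6. It was nearly absent from C1q macrophage-like (0.253%), plasma cell-like (0.313%), neutrophil-like (0.140%), B cell-like (0.164%), NK-like (0.162%) and CD8 T-like cells (0.177%), and from CD4 T-like cells (0 of 2897) and monocyte-like cells (0 of 381). Median depth does not order these classes, since plasma cell-like cells (17095 UMIs) were deeper than alveolar macrophage-like cells (13733 UMIs), and in CPM the epithelial, alveolar macrophage-like and C1q macrophage-like levels were 12.2, 5.69 and 0.250. Free RNA of a library would reach all its classes at a similar level. EGFP was at 4.05 CPM in macrophage cluster 6, and at 0 (CD4 T-like) to 0.811 CPM (NK-like) in the classes where it was nearly absent. These levels argue against free RNA as the main source of EGFP UMIs in alveolar macrophage-like and cluster 6 cells, though no separate test was run.

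In lymphocytes, further lists moved between groups. CD4 T-like cells had 5 of 5 measured MHC class II genes negative (median -1.03; camera adjusted p = 3.83e-07, with an estimated correlation adjusted p = 0.363), alongside the falls of the B cell genes Cd79a and Ebf1. In this class 0 genes were called with Scrublet doublets kept or with top-scoring doublets left out. Scrublet marked 13.5% and 0% of the cells with both hashtags in the Con libraries, against 30.1% and 19.5% in the mA1 libraries. Doublets with B cells were not tested as a source of these values. B cell-like cells were lower in cell cycle genes (median -0.39; adjusted p = 0.00529, with an estimated correlation 0.630) and NF-kB response (median -0.22; adjusted p = 0.0202, with an estimated correlation 0.630). Gamma-delta T-like cells went the other way for NF-kB response (median 0.28; adjusted p = 0.0224, with an estimated correlation 0.405) and immediate early genes (median 0.18; adjusted p = 0.0121, with an estimated correlation 0.405), and 11 of 12 mitochondrial genes were negative there (median -0.14; adjusted p = 1.18e-06, with an estimated correlation 0.176), as were 12 of 12 in neutrophil-like cells (median -0.23; adjusted p = 5.13e-04, with an estimated correlation 0.655). cDC2-like cells had 18 of 22 immediate early genes negative (median -0.19; adjusted p = 6.95e-05, with an estimated correlation 0.885). Cirbp, which encodes a cold-inducible RNA-binding protein, had values of 0.78 in B cell-like (adjusted p = 0.258), 0.66 in NK-like (0.0535) and 0.67 in CD8 T-like cells (0.0522), none passing.

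Clu and other epithelial transcripts were lower in lymphocytes of mA1 libraries, with Clu at 46.7 and 80.7 CPM in the Con and 22.9 and 12.2 CPM in the mA1 libraries. Doublets with epithelial cells are argued against as the source, since cells with at least 10 Clu UMIs held 0.000% of the Clu UMIs of lymphocytes (1505 UMIs in 1284 cells, at most 9 in a cell, against a median of 335 in epithelial cells). Whether free RNA from more epithelial cells in Con suspensions may be the source cannot be told: epithelial classes held 26.9% and 22.7% of all UMIs in the Con and 10.5% and 18.05% in the mA1 libraries, the lowest Con value 4.65 points above the highest mA1 value, but by cells the shares overlapped (10.4% and 4.43% against 4.04% and 6.08%), and within each group the library with the larger UMI share had the lower Clu, while the 16 markers together followed the UMI share in the Con (196 and 173 CPM) but not in the mA1 libraries (102 and 61.5 CPM). A single ratio of markers over the lymphocyte classes, which free RNA needs, was not decided either (chi-square over degrees of freedom 3.22, median of 1.27, 4.10, 6.998 and 2.33). A lower expression of Clu by lymphocytes of mA1 tumours stays open and was not tested, and the mA1 label is not matched by a rise in Malat1 that passed the test.

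Immediate early genes, which respond within minutes to handling, were lower in mA1 samples in 8 of 11 classes by their median, from -0.41 in tumour-like epithelial and -0.37 in NK-like to -0.03 in neutrophil-like cells. The Xist-expressing Con library is argued against as the whole cause in NK-like cells, where the median was -0.54 without it, but the median shrank to -0.14 in alveolar macrophage-like and turned to 0.14 in neutrophil-like cells. Without that library it moved further down in CD4 T-like (-0.31), cDC2-like (-0.28), B cell-like (-0.23) and cluster 6 cells (-0.23). It turned to -0.09 in CD8 T-like cells and stayed positive in gamma-delta T-like (0.17) and C1q macrophage-like cells (0.03). Handling that differed between libraries may be the cause, but each library holds tumours of 1 group only, so handling and group cannot be told apart. A response of the cells to the tumours themselves stays open and was not tested.

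Other splits of the 8 tumours into groups of 4 show whether chance can be excluded as the source of the gene counts, and in none of the 7 immune classes with calls could it be. The 35 splits include the real one, which is counted in each number of splits given here. Among them, as many genes as in the real one were called in 2 for alveolar macrophage-like (real 2, highest other 6), 6 for macrophage cluster 6 (2 and 7), 12 for B cell-like (1 and 76), 2 for NK-like (17 and 27), 5 for CD4 T-like (3 and 39), 2 for CD8 T-like (10 and 24) and 4 for gamma-delta T-like cells (2 and 7). Where the number is 2, the result rests on 1 other split. In C1q macrophage-like, neutrophil-like and cDC2-like cells the real split called 0 genes, so all 35 splits gave as many and the count tells nothing (highest other 15, 142 and 5). Splits that call several times the real count, such as those with 142, 76 and 39 genes, point to a structure of the samples, and in 5 classes the highest other split keeps the libraries whole. It sets both library 1 samples against both library 2 samples in alveolar macrophage-like and B cell-like cells, and Con library 1 with mA1 library 2 against the rest in NK-like, CD4 T-like and CD8 T-like cells. For gene lists chance could not be excluded either. As many were called in 6 splits for alveolar macrophage-like (real 11, highest other 17), 17 for macrophage cluster 6 (8 and 12), 34 for C1q macrophage-like (2 and 12), 21 for neutrophil-like (3 and 7), 31 for cDC2-like (2 and 15), 17 for B cell-like (5 and 10), 14 for NK-like (4 and 8), 26 for CD4 T-like (4 and 11), 34 for CD8 T-like (2 and 8) and 3 for gamma-delta T-like cells (5 and 5). The epithelial counts have 2 libraries per group and were not put to such splits.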
